A study of Escherichia coli with 4 samples.

How the data were processed

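Escherichia coli BW13711 was grown without oxygen in continuous culture, without or with 1% of a tannin extract from the bark of black wattle (Acacia mearnsii), per the labels and the design text. Each condition was measured on 2 Affymetrix E. coli Antisense Genome arrays, which carry probe sets for annotated genes and for intergenic stretches of both strands. The array replicates are numbered 2 and 8 for 0% tannin and 3 and 5 for 1% tannin. Per the design text both arrays of a condition came from culture at steady state and nothing names separate cultures, so p-values measure only the spread between these samples, which may be technical. The pH was 5.7 without and 5.3 with tannin, so tannin and pH changed together. Per the design text, residual DNA in the RNA was looked for by PCR and removed with DNase where needed. Which samples were treated is not given in the sources used here.

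The deposited values are intensity signals on a linear scale, made by the authors with MicroArray Suite 5.0 and further analysed in GeneSpring 5.0, per the submitters' processing notes and the design text. The 2% trimmed mean of each array was 150.0, so the arrays had been scaled to a common mean before deposit. The number of arrays limits the precision. The design text calls genes changed by more than 1.9-fold, after removal of genes that varied between duplicates, and counts 1498 of them.

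Of 7312 probe sets, 4345 represent E. coli genes, 2886 intergenic stretches, 59 phage or plasmid genes foreign to this chromosome, and 22 are manufacturer controls. Gene names come from the locus tag in the probe set's name, of which 4183 matched the RefSeq table of assembly ASM584v2 and 90 retired tags were named through the probe table; 72 kept the name in the file. In the probe table, 1409 of the gene probe sets have 1 gene symbol, 2836 have several, which list the gene in other strains, and 100 are not listed. A retired tag was named from an entry only where its gene IDs gave exactly 1 gene of the RefSeq table. No coordinates are given, because the build behind the array is not given in the sources used here. A gene with several probe sets was represented by the brightest, which left 4302 genes, 41 of them with more than 1 probe set. Probe sets of 2 of these genes, gatR and yjgX, moved in opposite directions by more than 0.5 on the log2 scale. Probe sets of a shared type (126) can bind near-identical genes.

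Signals below a common floor of 79.7, the median over arrays of the 20th percentile of gene probe sets, were set to it before taking log2, so changes of dim genes are understated. Genes at the floor on all 4 arrays (107) were not tested. The remaining 4195 were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values in the text come from limma, except those given against random lists. Intergenic probe sets were fitted separately. For a gene at the floor on both arrays of a condition the fold is a lower bound and is written "at least". The 52 gene lists were tested with camera of limma, with a preset inter-gene correlation of 0.01, and adjusted over all lists. No probe set matched ecnB and tisB. With an estimated correlation the adjustment gave many lists the same adjusted p of 0.553. Their unadjusted p in camera ran from 0.0332 to 0.340, so 0.553 is not a result of each list alone. In that setting camera rests on 2 residual degrees of freedom, so few lists could pass whatever their correlation. The arginine list, at an estimated correlation of -0.017, went from an unadjusted p of 5.07e-07 to 0.0332 in camera. A call lost there is therefore no measure of correlation alone, and the setting does not bear the call out either. The BaeSR list was chosen with knowledge of the study and is not independent evidence.

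Before the data were examined, the groups, the test, the floor, the lists, the alternatives and a rule for named genes were fixed. The rule takes the 10 largest increases and the 10 largest decreases that passed the threshold above the floor on all arrays. It adds the 3 largest bounds per direction, up to 4 members of each called list that passed in its direction, and every member of the BaeSR list; this gave 145 genes, of which the text names part. Alternatives fixed then were quantile normalization, median scaling, cyclic loess, no floor, a floor at the 40th percentile, a filter at the median level, no intensity trend, leaving out each array, averaging probe sets, the fold criterion of the design text, a joint fit of genes and intergenic probe sets, an estimated inter-gene correlation and ranks in camera. Chosen after seeing the data were scaling on 9 spike probe sets, subtraction of each array's median intergenic signal, and a comparison of lists with 10000 random lists matched on mean level. Leaving out 1 array leaves a lone array in its group, which is then assumed to vary like the other group.

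The test was tested on simulated data for this comparison with 4195 genes, where it recovered 78% of 2-fold and 96% of 4-fold changes, with 3.3% of calls false. With no gene changed it made 1 call. The simulation drew independent errors for each gene and no difference in signal spread between the arrays. The real arrays differ in that spread, so these rates do not carry over to the calls made here. Tables and plots were made with Python, pandas, scipy and matplotlib.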

Results

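Total RNA of E. coli was measured in 2 samples from anaerobic continuous culture without tannin and 2 from culture with 1% black wattle tannin extract. Both cultures were held at a dilution rate of 0.14 per hour and 37 °C and reached an optical density near 0.2. Median signals of the gene probe sets were 110 and 89.9 on the 0% tannin arrays (replicates 2 and 8) and 157 and 151 on the 1% tannin arrays (replicates 3 and 5). Across gene probe sets, log2 signals correlated with Pearson's r of 0.930 between the 0% arrays and 0.909 between the 1% arrays, and between 0.616 and 0.813 across the groups; genes are not independent replicates. The question asked of the comparison is how the bacterium's transcripts differ when it grows in the presence of tannins.

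With 1% tannin, spy, ibpB, ibpA and marA were among the genes that rose, and aroF, ompF, tyrA and cspG among those that fell. The periplasmic chaperone gene spy rose at least 11.97-fold, from a mean signal of 57.2 ± 7.66 to 1000.0 ± 425 (SD, n = 2 each). The gene aroF, for the tyrosine-sensitive first enzyme of aromatic amino acid synthesis, fell by 3.37 ± 0.27 (log2, SE), from 1534 ± 0.530 to 150.0 ± 27.2 (SD, n = 2 each). The porin gene ompF fell by 2.84 ± 0.26 and tyrA, which acts in tyrosine synthesis, by 2.82 ± 0.23. Adjusted p in limma was 0.00906 for each of these 4 genes.

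Of 4195 genes tested with limma, 2040 were called, 1492 higher and 548 lower with tannin (73.1% higher), and 2453 had an unadjusted p under 0.05. Of the 1492 higher, 873 were at the floor on both 0% arrays, so they could only rise and had no spread there. Of the 548 lower, 4 were at the floor on both 1% arrays. With no floor 1428 were higher and 654 lower, and among genes above the median level 352 and 638. The split depended on scaling: quantile normalization called 627 genes, 297 higher and 330 lower (47.4% higher), and median scaling called 751 higher and 1045 lower. Called in both the deposited and the quantile normalized values were 254 genes higher and 201 lower, and 4 were called in opposite directions. Cyclic loess called 9 genes, 8 higher and 1 lower. The median log2 change of all genes was 0.28 as deposited, 0.02 after quantile normalization, -0.10 with median scaling and 0.84 with scaling on spike probe sets, whose mean was 94.9 on 1% replicate 3 against 206, 211 and 195 on the other arrays, so that value rests mostly on 1 array. Leaving out 1 array gave 1116 calls without 0% replicate 2, 489 without 0% replicate 8, 1161 without 1% replicate 3 and 1494 without 1% replicate 5. The groups did not overlap in 79.1% of genes, against 33.3% for arrays that are exchangeable and without ties. The overlap was taken on floored values. The floor and the unequal signal spread of the arrays can raise this share by themselves, so the excess is no measure of changed genes. With the fold of 1.9 from the design text and no overlap between groups, 1036 genes passed, 502 higher and 534 lower, beside the 1498 the design text counts.

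The brightest genes in the absence of tannin tended to fall. Among these 420 genes 233 fell and 0 rose, with a median log2 change of -1.29. The dimmest 30% had a median of 0.59, but they lay at the floor on both 0% arrays. They were tested only where a 1% array exceeded the floor, so their change could not be negative. Before the floor was applied, the 5th percentile of gene signals was 28.0 and 8.46 on the 0% arrays. It was 88.1 and 69.8 on the 1% arrays. The log2 interquartile range of gene signals was 1.84 and 2.79 on the 0% arrays and 0.63 and 0.91 on the 1% arrays. Intergenic probe sets had median signals of 48.4 and 29.7 without tannin and 115 and 88.1 with it, whereas foreign phage and plasmid probe sets had 6.02 and 5.34 without and 3.16 and 4.80 with it. These values stand beside every gene group described here, which differ in their level without tannin.

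**Figure D1:**
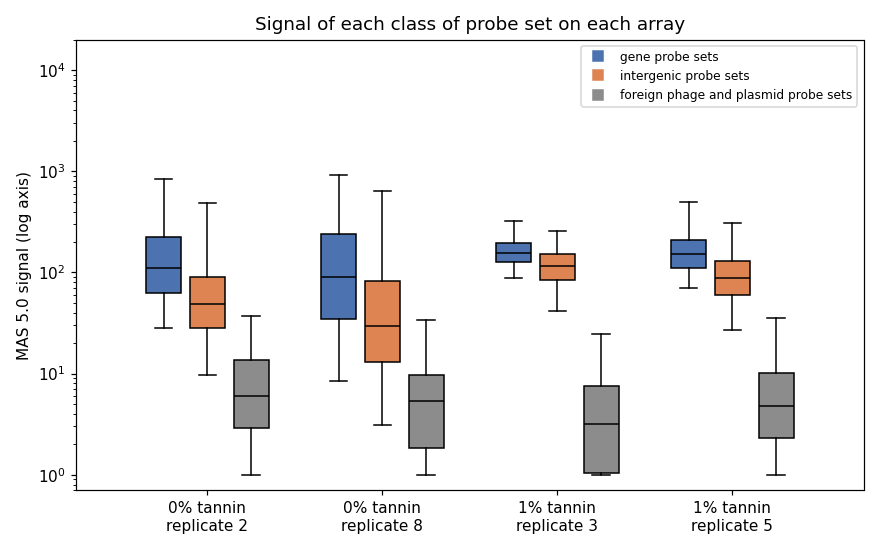
MAS 5.0 signal (log axis, values under 1 drawn at 1) of gene, intergenic and foreign probe sets on each of the 4 arrays; boxes span the quartiles with the median as a line, and whiskers the 5th to 95th percentile. Intergenic medians lie at 48.4 and 29.7 on the 0% arrays and at 115 and 88.1 on the 1% arrays.

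Genes of the BaeSR two-component system, which responds to envelope damage and controls drug efflux pumps, rose: 7 of 8 members were higher, and 7 adjusted over the list alone. Besides spy, mdtA rose by 2.18 ± 0.18 (log2, SE), from 87.8 ± 9.07 to 399 ± 41.8 (SD, n = 2 each). The other genes of that efflux operon, mdtB and mdtD, rose at least 2.31-fold and at least 2.67-fold, and mdtC rose by 1.08. The sensor gene baeS rose by 1.07 and the efflux pump gene acrD by 1.02, while the regulator gene baeR differed by 0.25 ± 0.17 without passing (adjusted p = 0.268 in limma) and by -0.24 after quantile normalization. The list lay 1.36 above the other genes in mean log2 change (camera of limma, adjusted p = 0.00660), and adjusted p = 0.553 with an estimated correlation. Without 1% replicate 3 it lay 1.43 above them (adjusted p = 0.231) and without replicate 5 it lay 1.38 above them (adjusted p = 0.203). After quantile normalization 4 members were called higher. The list was chosen with knowledge of the study and is not independent evidence of its direction.

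The phage shock genes, which respond to damage of the inner membrane, rose in 6 of 7 members (7 adjusted over the list alone). Among them pspA rose by 1.98 ± 0.20 (log2, SE), pspC by 1.68, pspB by 1.39 and pspD by 1.24. The list's mean difference from other genes was 1.16 (camera of limma, adjusted p = 0.0123), with adjusted p = 0.553 with an estimated correlation. Without 1% replicate 3 the difference was 1.20 (adjusted p = 0.217) and without 1% replicate 5 it was 0.98 (adjusted p = 0.272). The genes of 2 small heat shock chaperones also rose, ibpA by 2.66 ± 0.43 and ibpB at least 8.02-fold. The regulator marA of multidrug resistance rose at least 5.69-fold and its repressor gene marR by 1.41. The periplasmic gene cpxP, part of the Cpx envelope response, rose by 1.71, glgS by 1.87 and the phosphate-binding protein gene pstS by 1.45. The lists these genes belong to were not called for Cpx envelope stress (3 of 11 higher, 3 adjusted over the list alone; camera of limma, adjusted p = 0.949), multidrug efflux (12 of 32 higher and 1 lower, 8 and 0; adjusted p = 0.574) or heat shock (6 of 20 higher, 6; adjusted p = 0.413). The insertion sequence genes insF2 and yi82_1 rose by 1.81 and 1.61, on probe sets shared by near-identical copies, so the copy is uncertain. In limma the named genes of this group had an adjusted p between 0.00906 and 0.0178.

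**Figure D2:**
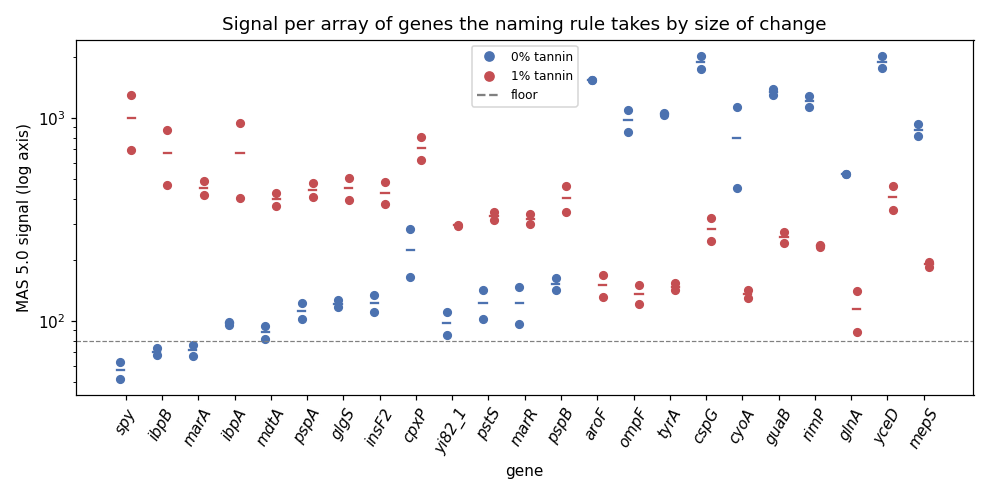
MAS 5.0 signal (log axis) per array for the 10 largest increases and 10 largest decreases among called genes above the floor on all arrays, and the 3 largest increases from the floor, in blue for 0% and red for 1% tannin; bars are means of 2 arrays and the dashed line is the floor of 79.7. The signal of spy lies below the floor without tannin and has a mean of 1000.0 with it, while aroF goes from 1534 to 150.0.

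The lists for ribosomal proteins, translation factors, RNA polymerase, protein secretion and cold shock were called lower as deposited, each with adjusted p = 0.553 with an estimated correlation. Of 54 ribosomal protein genes 41 were lower and 0 higher (48 lower adjusted over the list alone), among them rpsF by -2.20, rpsR by -2.14 and rplM by -2.08 in log2. Of 35 genes for aminoacyl-tRNA synthetases and translation factors 14 fell, 1 rose and 20 were not called (11 and 1 adjusted over the list alone), with infB at -1.62, and of 12 for RNA polymerase and transcription factors 8 fell (8), with nusA at -2.01. In protein secretion 11 of 16 fell (12), with secE at -1.65. The mean differences from other genes were -1.77, -0.95, -1.09 and -1.13 (camera of limma, adjusted p = 1.65e-19, 2.61e-09, 4.13e-05 and 1.91e-07). Against random lists of the same mean level the synthetase, RNA polymerase and secretion lists lost the call (differences -0.22, -0.29 and -0.29; adjusted p = 0.0978, 0.192 and 0.124). With cyclic loess the first pair lost it too (adjusted p = 0.190 and 0.0641 in camera of limma). After quantile normalization the ribosomal difference was -0.61, with 13 genes called lower. Of 10 cold shock genes 8 fell (9), cspB by -3.03, cspG by -2.74 and cspI by -2.04 (difference -2.03, adjusted p = 5.54e-07).

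The lists for purine, pyrimidine and arginine synthesis and for nitrogen starvation were called lower as deposited, each with adjusted p = 0.553 with an estimated correlation. In purine synthesis 13 of 23 were lower and 1 higher (15 and 1 adjusted over the list alone), with guaB at -2.38 and purM at -1.98, and in pyrimidine synthesis 8 of 13 were lower and 1 higher (9 and 1), with pyrB at -1.63. Arginine synthesis had 9 of 14 lower (11), with the arginine uptake gene artP at -1.96, carA at -1.66 and carB at -1.59; carA and carB also serve pyrimidine synthesis. In the nitrogen starvation list 6 of 29 fell, 3 rose and 20 were not called (5 and 3 adjusted over the list alone; median log2 change -0.14), with the glutamine synthetase gene glnA at -2.24, nac at -1.83 and gltI at -1.73. The differences from other genes were -1.07, -1.07, -1.10 and -0.47 (camera of limma, adjusted p = 5.54e-07, 3.48e-05, 3.76e-06 and 0.00697). The nitrogen list had an adjusted p of 0.0679 without 1% replicate 5.

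Of the other amino acid lists 4 were called lower as deposited, each with adjusted p = 0.553 with an estimated correlation. Aromatic amino acid synthesis had 8 of 22 lower and 1 higher (8 and 1 adjusted over the list alone), histidine synthesis 4 of 8 lower (5), methionine synthesis 5 of 15 lower and 1 higher (4 and 1), and the glutamate, threonine, lysine and proline list 8 of 23 lower (8). Examples were hisF at -1.28, metF at -1.83, metE at -1.54 and glyA at -1.75 in log2. After quantile normalization the methionine list (adjusted p = 0.0809 in camera of limma) and the glutamate list (adjusted p = 0.0546) were no longer called. All 4 lists lost the call with cyclic loess (adjusted p from 0.126 to 0.236 in camera of limma). They also lost it against random lists of the same mean level (adjusted p from 0.0978 to 0.157), and kept it with intergenic subtraction. As deposited the 4 lists had an adjusted p from 5.20e-05 to 0.000609. Branched chain amino acid synthesis was not called, with 3 of 20 lower and 1 higher (0 and 0; adjusted p = 0.179), a median log2 change of -0.02 and a difference from other genes of -0.27 as deposited and 0.17 after quantile normalization, so its direction turned with the scaling. In contrast, cysteine and sulfur assimilation was called higher (adjusted p = 0.0243, and adjusted p = 0.553 with an estimated correlation).

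In energy metabolism, ndh, for an NADH dehydrogenase, fell by 2.80 ± 0.24 (log2, SE) and the cytochrome oxidase genes cyoA and cydA by 2.40 ± 0.46 and 1.85 ± 0.29. The signal of cyoA was 1133 on 0% replicate 2 and 454.7 on 0% replicate 8, so the size of its fall is uncertain. After quantile normalization the changes of ndh, cyoA and cydA were -2.69, -2.36 and -0.75. Aerobic respiration had 9 of 31 genes lower and 2 higher (6 and 2 adjusted over the list alone; camera of limma, adjusted p = 0.00697, and adjusted p = 0.560 with an estimated correlation). It was not called after quantile normalization (adjusted p = 0.0742) or without 0% replicate 2 (adjusted p = 0.182). ATP synthase had 7 of 9 lower (8), with atpG at -1.38 (adjusted p = 7.74e-05, and adjusted p = 0.553 with an estimated correlation), and was not called after quantile normalization (adjusted p = 0.263). The citric acid cycle list had 3 of 23 lower and 1 higher (0 and 0), sdhC, lpd and aceA being the lower ones, and had a camera adjusted p of 0.0197, and adjusted p = 0.583 with an estimated correlation. Of the fits leaving out an array, the one without 0% replicate 8 called it, and the adjusted p was 0.446, 0.0501 and 0.0686 without 0% replicate 2, 1% replicate 3 and 1% replicate 5. Anaerobic respiration had 25 of 51 higher and 2 lower (27 and 2), with dcuC at 1.23 and nrfA at 1.09 (camera adjusted p = 0.0123, and adjusted p = 0.553 with an estimated correlation). The adjusted p was 0.0982 without 1% replicate 3 and 0.304 without 1% replicate 5.

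Envelope, cell cycle, regulator and transport lists lay lower, each with adjusted p = 0.553 with an estimated correlation. Fatty acid and phospholipid synthesis had 9 of 25 lower (9 adjusted over the list alone), with plsX at -1.96, DNA replication and division 10 of 29 (8), with ftsK at -1.12, and the sigma E list 6 of 19 lower and 1 higher (4 and 1), with the chaperone gene surA at -1.22. Peptidoglycan synthesis had 7 of 24 lower and 2 higher (0 and 0), with mreB at -0.98, and lipopolysaccharide genes 8 of 28 lower and 2 higher (0 and 0), with arnA at -1.84. Nucleoid proteins and global regulators had 7 of 18 lower and 1 higher (7 and 1), with fnr, the regulator of anaerobic genes, at -1.95 and fis at -1.50. After quantile normalization fnr was at -1.99 and fis at -0.34 (adjusted p = 0.0346 and 0.161 in limma). Peptide and amino acid transport had 9 of 25 lower and 5 higher (12 and 6), with oppF at -1.92. As deposited these lists had an adjusted p from 2.68e-06 to 0.0243 in camera of limma. Without 0% replicate 2 lipopolysaccharide (adjusted p = 0.0835) and peptide transport (adjusted p = 0.0920) were not called. Of these lists, peptidoglycan and DNA replication were also called after quantile normalization (adjusted p = 0.00194 and 0.0170 in camera of limma), and the others were not. DNA replication lost the call with cyclic loess (adjusted p = 0.190 in camera of limma) and against random lists of the same mean level (adjusted p = 0.124). Peptidoglycan kept it in both (adjusted p = 0.0416 and 0.0236).

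The lists that rose besides these had adjusted p = 0.583 for flagella, 0.643 for curli and 0.553 for the others with an estimated correlation. Flagella and chemotaxis had 33 of 52 higher and 1 lower (36 and 1 adjusted over the list alone), alternative sugar use 46 of 81 higher and 3 lower (49 and 4), phosphate starvation 17 of 29 higher (19), iron uptake 17 of 37 higher and 3 lower (23 and 3), cysteine and sulfur assimilation 16 of 28 higher (17), aromatic compound degradation 20 of 29 higher (20), and curli and biofilm 8 of 18 higher (8). Their median log2 changes were 0.58, 0.58, 0.61, 0.59, 0.58, 0.69 and 0.54. The dimmest 30% of genes had 0.59, but they lay at the floor on both 0% arrays, so their change could not be negative. That value is therefore no measured shift to set the lists against. The 7 lists share this limit. Their median signals on the 0% arrays ran from 43.0 for flagella to 66.4 for iron uptake, below the floor of 79.7. Many members had little or no room to fall, so these counts and medians are partly fixed by the floor. Examples from the 7 lists were malG, of maltose uptake, at 1.43, the chemotaxis receptor gene aer at 1.26 and the phosphonate uptake gene phnD at 1.36. As deposited the 7 lists had an adjusted p from 0.00031 to 0.0322 in camera of limma. Iron uptake was not called without 0% replicate 2 (adjusted p = 0.126), and curli without 0% replicate 2 or 8 (adjusted p = 0.335 and 0.204). Cysteine and sulfur assimilation was called only without 0% replicate 2 among the fits leaving out an array (adjusted p = 0.0267, against 0.0985, 0.135 and 0.111 without 0% replicate 8, 1% replicate 3 and 1% replicate 5). After quantile normalization flagella, sugar use and curli were called (adjusted p = 0.0289, 0.0387 and 0.0387 in camera of limma), and the others were not. With cyclic loess none of the 7 lists was called (adjusted p from 0.202 to 0.681 in camera of limma). Against random lists of the same mean level sugar use, phosphate starvation and curli kept the call (adjusted p = 0.0451, 0.00693 and 0.0013). The other lists, flagella among them, lost it there (adjusted p from 0.0978 to 0.355).

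**Figure D3:**
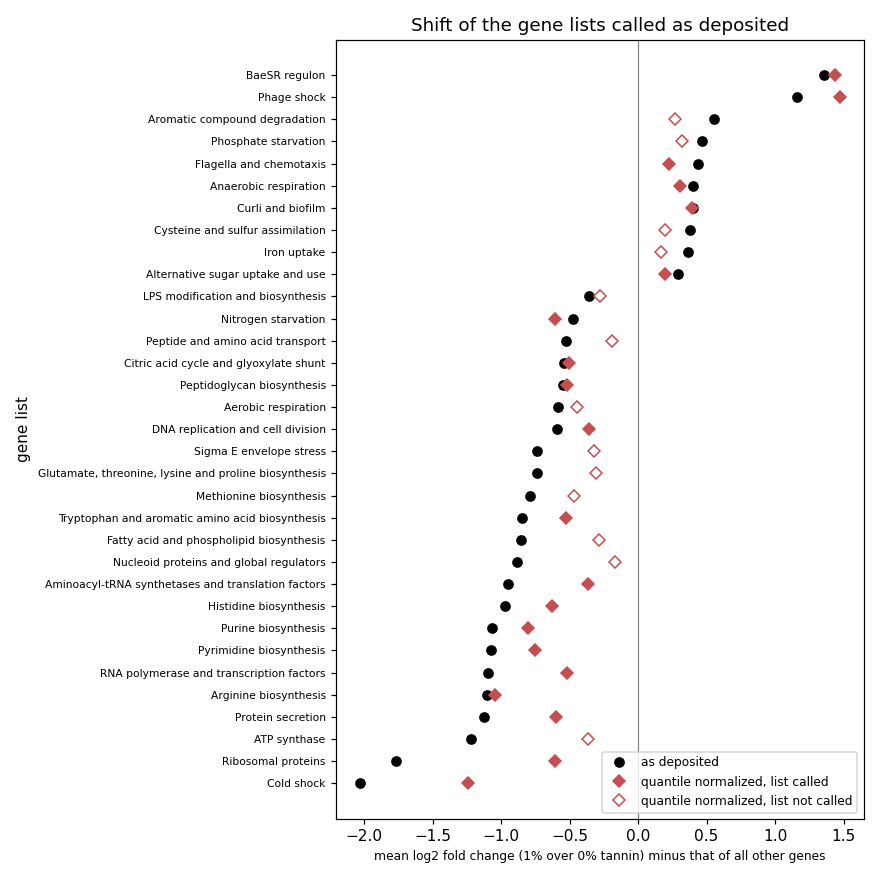
Mean log2 change (1% over 0% tannin) of each of the 33 called lists minus that of the other genes, as deposited (black) and after quantile normalization (red, filled where called). The ribosomal protein list moves from -1.77 to -0.61, and the BaeSR list from 1.36 to 1.44.

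In all, 33 of 52 lists were called, 10 up and 23 down, and 20 of them were also called in the same direction after quantile normalization. Those called also with cyclic loess, intergenic subtraction and matched random lists were 10: ribosomal proteins, cold shock, purine, pyrimidine, arginine, peptidoglycan and nitrogen starvation lower, and BaeSR, phage shock and anaerobic respiration higher. The 3 that rose kept their direction but lost their call when either 1% array was left out, and nitrogen starvation lost it without 1% replicate 5. After quantile normalization 3 of 51 anaerobic respiration genes were called higher and 1 lower. With an estimated correlation 0 lists were called by camera of limma, and 2 had an unadjusted p under 0.05. That setting rests on 2 residual degrees of freedom, so it could hardly call a list and does not decide between them. The 19 lists not called as deposited, such as oxidative stress, SOS, hydrogenases and fermentation, had an adjusted p between 0.0757 and 0.949. Of the 145 genes taken by the naming rule, 114 kept their side of the threshold without 0% replicate 2, 81 without 0% replicate 8, 50 without 1% replicate 3 and 64 without 1% replicate 5, and 75 after quantile normalization.

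Of 2287 intergenic probe sets tested with limma, 132 were called, 66 higher and 66 lower, and 833 had an unadjusted p under 0.05. With no floor 1747 were called, 1490 higher and 257 lower. After quantile normalization 2 were called, and without 0% replicate 2 or 0% replicate 8 the count was 0 (367 and 235 at an unadjusted p under 0.05), against 1210 without 1% replicate 3 and 1570 without 1% replicate 5.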

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

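All tests in this part were chosen after the results were seen. No probe set outside the comparisons met the rule for a signal above the 0% tannin arrays.

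On the 1% tannin arrays dim genes and intergenic probe sets lay higher and bright genes lower. Background not tied to E. coli sequence is argued against, since foreign probe sets moved by a median of -0.35 (log2) while intergenic ones moved by 1.32. A candidate explanation is chromosomal DNA labelled with the RNA. The foreign level was taken as each array's 95th percentile of foreign probe sets, 24.8 to 37.1. Outside a block of adjacent genes from yahI to mhpF, 3 of 4316 gene probe sets lay at or below it on both 1% arrays, against 339 on both 0% arrays. The block was picked as a run of neighbouring genes at or below that level on every array. Of its 29 probe sets 25 were so on both 1% arrays, and by that choice the block staying low is no test. A simulation for this comparison added only a constant signal, with no gene changed. Calls by limma were 171 genes higher and 31 lower, below the 1492 and 548 observed, and 0 and 0 after quantile normalization. The floor was set anew on the simulated arrays, so the number of genes tested can differ from 4195. The profile was assumed, so the simulation decides nothing. Broad transcription brought on by tannin or pH would also give the intergenic 1.32, but not the gap of 0.40 between the 0% arrays (0.51 for intergenic against 0.11 for foreign probe sets), which does not exclude it either, and with no DNA control the pair cannot be told apart.

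Ribosomal protein genes lay lower with tannin. Compression of every bright gene alike cannot be told apart from a fall of their own: after quantile normalization their median difference (log2) from the 200 genes nearest each in 0% tannin level was 0.21 and 0.19 on the 0% arrays and -0.23 and -0.07 on the 1% arrays. Members brighter than their matched genes come closer to them by compression alone, and the nearer 1% array lay only 0.071 below 0, less than the 0.16 between the 1% arrays. Earlier tests were replaced after their results were seen: a further -0.46 beyond random lists of the same mean level, and a distance of 0.26 between the groups that ignored the brighter start, argued against compression, while -0.28 set against the spread of single genes left it open. A response to tannin or to the lower pH stays open at a list difference of -0.61 after quantile normalization, because tannin, pH and culture differ together, and the list had adjusted p = 0.553 as deposited with an estimated correlation in camera of limma.

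Phage shock and BaeSR genes lay higher with tannin, on lists singled out after their values were seen, BaeSR also with knowledge of the study. These genes rose by more than genes of the same level. After quantile normalization the 15 members were compared with the 200 genes nearest each in 0% tannin level. Their median difference (log2) was 1.63 and 1.10 on the 1% arrays, which are 0.53 apart. It was -0.03 and 0.00 on the 0% arrays, where the matching itself brings it near 0. The matched genes' own changes had an interquartile range of 0.83. The lists were singled out from these values. The excess over the rise of dim genes is therefore described, and its cause is not decided. Earlier tests, replaced after their results were seen, gave the same direction. They pooled the heat shock list, which was not called as deposited, or used the spread of single genes. Both lists had adjusted p = 0.553 with an estimated correlation in camera of limma. A response to tannin or to the lower pH may account for the phage shock difference of 1.47 after quantile normalization and cannot be told apart from a difference between single cultures.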

How the results depend on the processing

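Scaling on spike probe sets, intergenic subtraction and matched random lists were chosen after seeing the data. The cause of the differences was not tested, except that a filter tests fewer genes and leaving out an array uses fewer samples. Intergenic subtraction also tested fewer genes, 2647 against 4195 as deposited. An estimated correlation leaves camera 2 residual degrees of freedom. Genes called numbered 2040 (1492 higher, 548 lower) as deposited; 627 (297, 330) after quantile normalization; 9 (8, 1) with cyclic loess; 1290 (843 higher) with a floor at the 40th percentile; 990 (352 higher) above the median level; 172 (24, 148) with spike scaling, where 1% replicate 3 has a spike mean of 94.9 and the others 195 to 211; and 50 (16, 34) with intergenic subtraction. Median scaling gave 751 higher and 1045 lower. The fold criterion without overlap gave 1036, and with adjusted p 897. Leaving out each array gave 489 to 1494 genes, 273 to 1119 higher and 174 to 437 lower. Intergenic calls, 132 as deposited, were 2 after quantile normalization, 0 with cyclic loess (331 at an unadjusted p under 0.05 in limma), 1747 with no floor, 0 with the 40th percentile floor (451 unadjusted), 280 above the median level, 443 without the trend, 26 with spike scaling, 1 with subtraction, 672 in a joint fit, and 0 to 1570 leaving out an array. Lists called, 33 as deposited, were 15 with cyclic loess, 18 against matched lists and 0 with an estimated correlation, and 29 to 31 leaving out an array. The BaeSR shift of 1.36 kept its direction, ranging from 1.21 to 1.43 leaving out an array, and lost its call without either 1% array and with an estimated correlation (1.36, adjusted p = 0.553 in camera of limma; over alternatives 4.5e-05 to 0.553). Of the 145 genes taken by the naming rule, those that turned in direction were baeR (-0.24 after quantile normalization, -0.38 with median scaling, -0.094 with cyclic loess), atpH (0.014 after quantile normalization), and yfdG and yehS (0.037 and 0.029 with spike scaling). For these genes 1262 other values kept direction and side of the threshold and 733 lost the call, and for the called lists other than BaeSR 414 and 129. Other genes and lists are not in these counts, and some turned: 4 genes were called in opposite directions as deposited and after quantile normalization, and the acid resistance list went from -0.27 to 0.38. Of the 145 genes 7 kept the call with cyclic loess. Signal over background limits dim genes: 873 of those called higher were at the floor on both 0% arrays.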

Other observations

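The heat shock list, fixed before the data were examined, was not called as deposited: 6 of 20 genes were higher and 0 lower (camera of limma, adjusted p = 0.413, and adjusted p = 0.834 with an estimated correlation), with a mean difference from other genes of 0.52. After quantile normalization 11 were called higher and the list was called, with a difference of 1.15 (adjusted p = 2.34e-06). The list was also called with cyclic loess (1.15, adjusted p = 1.48e-07) and intergenic subtraction (1.28, adjusted p = 1.02e-05) in camera of limma. Against random lists of the same mean level the difference was 1.14 (adjusted p = 0.0013). Subtraction and random lists were chosen after seeing the data. Chaperone genes chosen after their values were seen gave log2 changes of 0.55 as deposited and 1.68 after quantile normalization for dnaK, 1.02 and 2.05 for groS, and 0.98 and 1.73 for grpE. The acid resistance list had 3 of 21 higher and 2 lower as deposited (adjusted p = 0.186, and adjusted p = 0.643 with an estimated correlation), with a mean difference of -0.27. After quantile normalization it was called higher, with a difference of 0.38 (adjusted p = 0.0387), so its direction turned with the scaling.

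Genes for tRNA, a group chosen after its values were seen, were called lower in 27 of 79 cases and higher in 0 by limma, with a median log2 change of -1.21. After quantile normalization 10 were called lower, with a median of -0.22, and with cyclic loess 0 were. The tRNA genes argX, serT and proM changed by -2.12, -1.84 and -1.62 as deposited and by -2.03, -1.84 and -1.80 after quantile normalization. Of the 79, 61 lie on probe sets shared by near-identical copies.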
